A study of Mus musculus with 8 samples.

How the data were processed

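RNA from whole colon tissue of 8 mice was measured on Affymetrix arrays after labelling with the manufacturer's kit for small amounts of RNA, with 1 array for each mouse. Group and replicate number were taken from the sample titles, which give 4 mice on PBS and 4 on hBD-2. The deposited table holds log2 expression values for 22203 probe sets, and the submitters' processing notes name the R package oligo and the method RMA, with no version. RMA corrects background, makes the distributions of all arrays alike by quantile normalization and summarises probes to 1 log2 value per probe set, so that an overall shift of expression between mice would not be visible. The genome build of the array design is not given in the sources used here, and no coordinates are printed.

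The platform annotation named 1 gene for 19572 probe sets, several for none, and 2631 were unnamed here. All named probe sets matched the gene table of the assembly GRCm38.p6 through their gene identifiers, which changed no symbol. Where a gene had more than 1 probe set (55 genes), the probe set with the highest mean over the 8 arrays was kept, which set 67 aside and left 19505 genes. No array pair was identical. Signal over background cannot be read from these values, and no dim probe set was removed in the main setting.

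Differences were tested on the log2 values as deposited with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as hBD-2 minus PBS, two-sided, with Benjamini-Hochberg adjustment over the 19505 genes, a threshold of 0.05 and no minimum fold. Standard errors are the moderated ones, and 95% intervals are built from them. The labels name no test. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with the other genes, with adjustment over the 43 lists of at least 5 measured members. Beside it stand camera with an estimated correlation, fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, and a two-sided exact permutation test of each list's mean per mouse. With 35 distinct splits of 8 mice into 4 and 4, the smallest p of that test is 0.0286. Members of a list were also adjusted over the list alone.

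The 44 lists, with 963 entries of which 865 were measured, were fixed before the data were examined, as were the tests and the rule for naming genes. They cover immune and stromal cell types, epithelial cell types, inflammatory and metabolic pathways, and checks for colon position, neighbouring tissue and sex. Few genes are shared between lists. For example, 1 of the 24 matrix genes, none of the 20 macrophage markers and 2 of the 27 chemokines stand in another list, and 21, 14 and 20 of them lie above the median of all genes. The rule named, in each direction, the 12 genes with the largest change past the threshold. Missing places were filled from genes whose groups did not overlap with an unadjusted p under 0.01, by size of change and given as values only. It also named the 4 members with the lowest p in each list that passed, 2 in every other list, and a set of disease genes such as Ifng, Tnf, Cd4 and Muc2 wherever measured. Gene models without a proper name were skipped.

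The pipeline was tested on simulated arrays of 4 against 4 with 19505 genes, of which 200 were changed, in 20 simulations. Of changes of 0.5, 1 and 2 log2 units, 56.3%, 92.1% and 99.4% were called in the right direction, and 5.15% of calls fell on unchanged genes. A list shifted by 0.3 log2 units was called in 100% of simulations. The simulated genes varied independently of one another, whereas genes of real lists vary together (estimated correlation 0.393 for the matrix list). These rates therefore do not show how reliable the list calls are on the real arrays. The rates for genes likewise hold for 200 changed genes and independent noise, and do not give the share of real changes found here.

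The alternatives were an intensity trend with a robust prior, leaving out the lowest 25% or 50% of probe sets, centring each array on its median, repeating the quantile normalization, averaging the probe sets of a gene, array weights, the replicate number as a block, leaving out each array in turn, a log2 minimum of 1, a threshold of 0.1, testing all probe sets, and the other list tests. Leaving out hBD-2 1 and hBD-2 3 together, and fitting the mean of the posterior colon identity genes as a covariate, were added after the data were seen. Principal components were computed on the genes tested, and figures were drawn with matplotlib 3.10.9.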

Results

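Gene expression was profiled in whole colon tissue from 8 mice with acute graft-versus-host disease, in which transplanted donor T cells attack tissues of the recipient. BALB/c recipients had been lethally irradiated and given C57BL/6 bone marrow cells together with T cells on day 0. From day 0 to day 7 the mice received either PBS or 1.2 mg/kg hBD-2 by mouth, and the colon was taken on day 7. hBD-2 is human beta-defensin 2, a small antimicrobial peptide made by epithelial cells. There were 4 mice in each group and 1 array per mouse, and the comparison asks how hBD-2 affected expression in the diseased colon. The array medians lay between 6.77 and 6.82 log2 units, and the number of arrays limits the precision of every value below. Changes are log2 differences, hBD-2 minus PBS.

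The arrays hBD-2 1 and hBD-2 3 stood apart from the other 6. On the first principal component, which held 34.6% of the variance, they lay at 25.2 and 25.4, while the others lay between -14.9 and -2.45. They correlated with each other at r = 0.9955 across genes. In these arrays Hoxb13, a homeobox gene of the most posterior body axis, reached 9.06 and 9.32 log2 units, against 4.73 to 7.22 in the other 6. Hoxd13 reached 6.20 and 6.03, against 4.09 to 4.49. Scnn1g, a subunit of the epithelial sodium channel of the distal colon, stood at 7.78 and 6.99, against 5.44 to 5.82. Fabp2, an intestinal fatty acid binding protein, was at 6.75 and 7.00, against 8.07 to 9.72. PBS 3 and PBS 4 were intermediate for Hoxb13, at 7.22 and 6.76, and for Insl5, at 8.71 and 8.21. In Hoxd13 they did not stand out (4.46 and 4.49, against 4.48 in hBD-2 4). Leaving out hBD-2 1 and hBD-2 3 therefore does not make the groups alike in Hoxb13. Hoxb13 and Fabp2, and Insl5, Fxyd4 and Mettl7b in the plot of colon genes, were picked after the principal components had been seen. The list of 11 posterior colon identity genes, fixed beforehand, had a mean difference of 0.34 between the groups, 0.061 without the 2 arrays, and did not pass the list test (adjusted p = 0.252 by limma's camera). Values without these 2 arrays, an alternative added after the data were seen, are given for each called list whose call they end or whose mean they move by over 1.5 times.

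**Figure D1:**
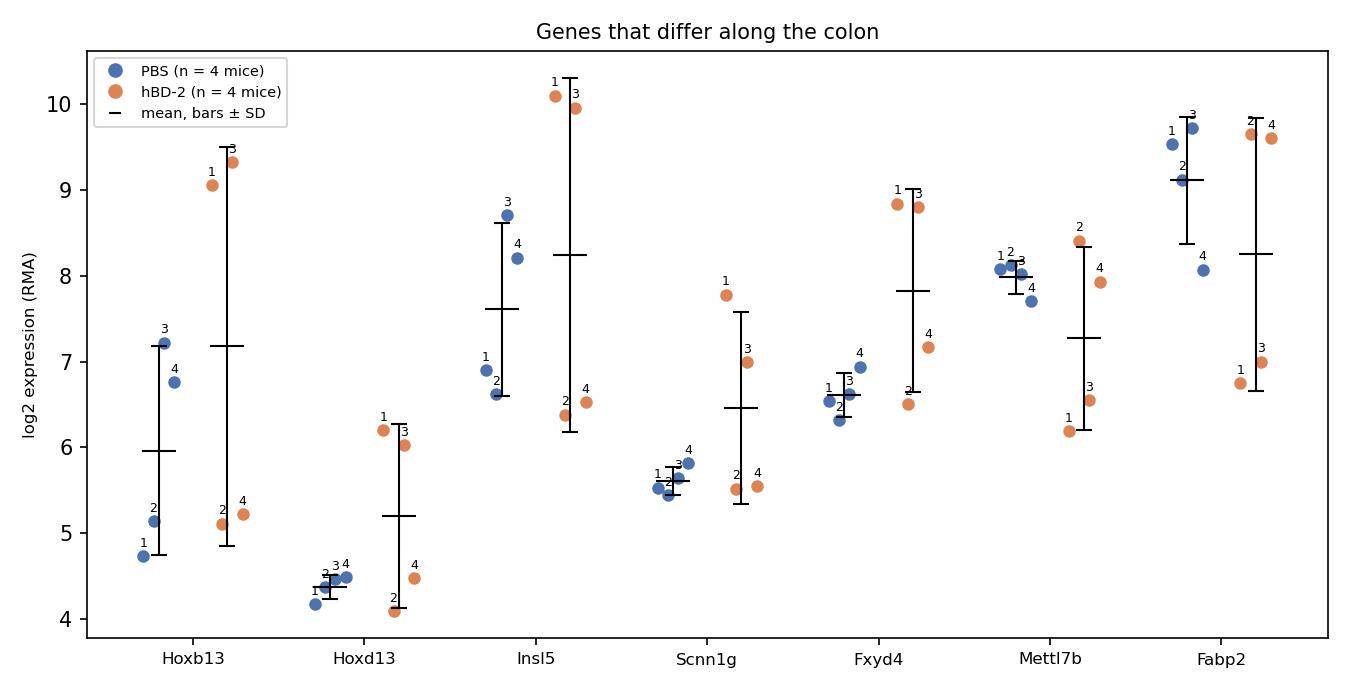
Log2 expression (vertical axis) of 7 genes that differ along the colon, with 1 point per mouse, the replicate number above it, and the mean with SD for PBS (blue, n = 4) and hBD-2 (orange, n = 4). The arrays hBD-2 1 and hBD-2 3 lie together and apart from hBD-2 2 and hBD-2 4, for example at 9.06 and 9.32 against 5.11 and 5.22 for Hoxb13.

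Of 19505 genes tested, 8 passed an adjusted p of 0.05, and all 8 were lower in the hBD-2 mice. Aif1, an actin-binding protein of macrophages, fell 1.94-fold, from 7.08 ± 0.22 to 6.12 ± 0.18 log2 units (SD, n = 4 each). The myeloid C-type lectin receptor Clec5a fell 1.86-fold, and Fcer1g, the signalling chain shared by several Fc receptors, fell 1.75-fold. Cd84, a leukocyte receptor of the SLAM family, and Lilr4b, another leukocyte receptor, changed by -0.68 (SE 0.080) and -0.63 (SE 0.079). The other 3 were Pde1a, a calmodulin-dependent phosphodiesterase, at -0.79 (SE 0.089), the matrix proteoglycan Aspn at -0.70 (SE 0.086), and the secreted signal Bmp5 at -0.63 (SE 0.074). For each of the 8 genes, all 4 hBD-2 mice lay below all 4 PBS mice. Adjusted p-values from limma ran from 0.0410 for Bmp5, Pde1a, Aspn, Cd84 and Lilr4b to 0.0486 for Clec5a.

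**Figure D2:**
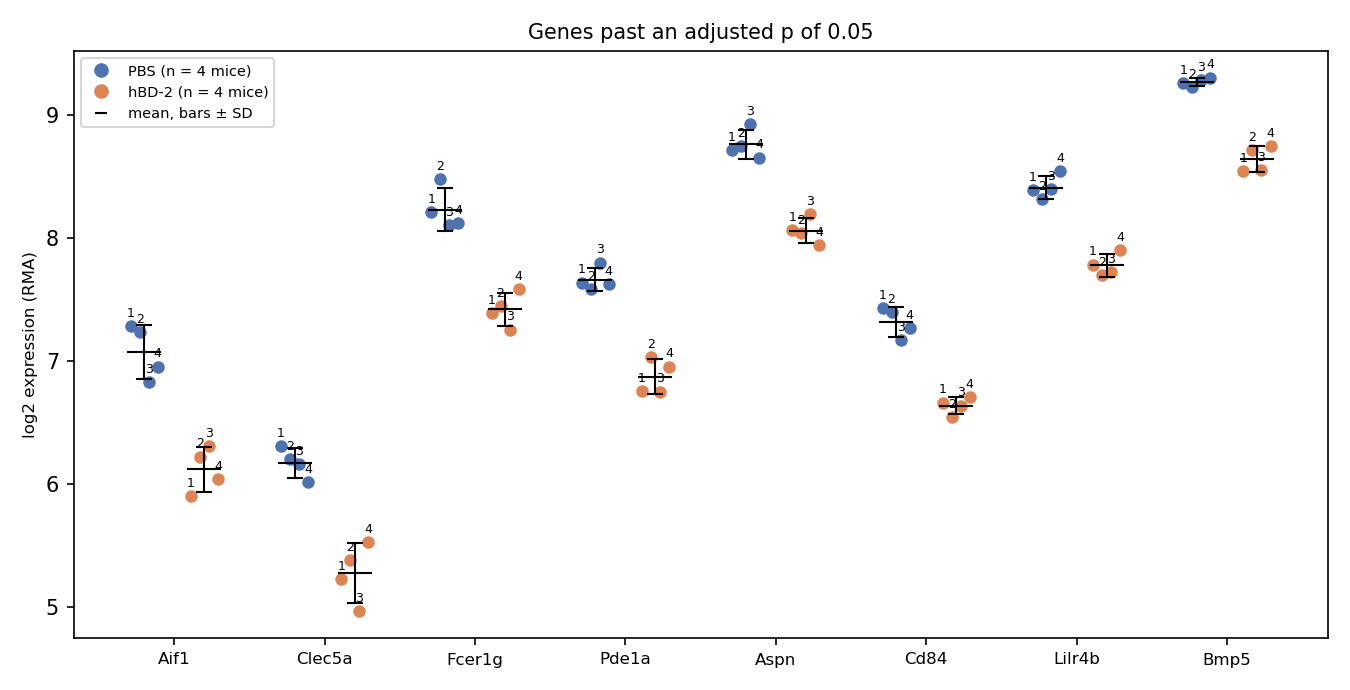
Log2 expression (vertical axis) of the 8 genes past an adjusted p of 0.05, with 1 point per mouse, the replicate number above it, and the mean with SD for PBS (blue, n = 4) and hBD-2 (orange, n = 4). In every gene the hBD-2 mice lie below the PBS mice, for example between 5.90 and 6.31 against 6.83 and 7.29 for Aif1.

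At an unadjusted p under 0.05 there were 2309 genes, 1142 higher and 1167 lower, where chance gives 975 on average. That number spreads widely, since other splits of the 8 mice into 4 and 4 gave 342 to 2265. The 2265 came from a split that kept 3 mice of each group together and so carries part of any group difference. Splits with 2 mice of each group on either side gave 342 to 1665. The groups did not overlap in 1250 genes, 6.41% of those tested, where chance gives 2.86% on average. None of the 8 calls was kept when PBS 1, 2, 3 or 4, hBD-2 1 or hBD-2 3 was left out singly, or hBD-2 1 and hBD-2 3 together: limma then passed 0 genes, with 1678 to 2771 at an unadjusted p under 0.05, while the changes of the 8 genes with single arrays left out stayed between -1.04 and -0.59. Without hBD-2 2 there were 11, 2 of them shared with the 8, without hBD-2 4 there were 9, with 6 shared, and limma with an intensity trend and robust prior passed 91, of which 85 were lower.

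Further genes had larger differences that did not pass. Atp6v0d2, a subunit of the vacuolar proton pump, was at -1.26 (SE 0.20, adjusted p = 0.0634 by limma). The Fc receptor Fcgr4 was at -1.09, the scavenger receptor and fatty acid transporter Cd36 at -1.06 and the collagen cross-linking enzyme Lox at -1.02. On the other side no gene passed. Among genes with a proper name, an unadjusted p under 0.01 and groups that did not overlap, the largest differences were Ctse, encoding the protease cathepsin E, at 0.97 (SE 0.27), Selenbp1 at 0.97, Nxpe5 at 0.85 and the chloride channel family member Clic6 at 0.80. Kyat1, Ttll6, Selenbp2, the gap junction gene Gjb1, the glutathione transferase gene Gstm6, the phospholipase gene Pla2g3, Fyb2 and Ceacam18 followed at 0.56 to 0.72, with adjusted p from 0.0715 to 0.243 in limma. Without hBD-2 1 and hBD-2 3, Ctse was at 0.42, Selenbp1 at 0.54, Clic6 at 0.50 and Kyat1 at 0.27. In the same setting Ttll6 was at 0.32, Selenbp2 at 0.42, Gstm6 at 0.35, Pla2g3 at 0.35 and Lox at -0.57. The other genes of this paragraph moved by at most 1.5 times. Of the 174 genes named by rule, 50 moved by over 1.5 times or changed direction with some single array left out and 66 with that pair left out, and none of the 8 that passed was among them.

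Of the 43 gene lists tested, 22 passed limma's camera with a preset correlation, 15 lower and 7 higher in the hBD-2 mice. None passed with an estimated correlation, where 7 had an unadjusted p under 0.05, and limma's fry passed 2. The exact permutation test of list means per mouse, two-sided, gave 10 lists its smallest possible p of 0.0286, which became 0.123 after adjustment. With hBD-2 1 and hBD-2 3 left out, 13 lists passed, all of them among the 22, and with the posterior colon score as a covariate 13 passed, also all among the 22, and the 9 that lost their calls were the same in both. The 2 settings are not separate checks, since the score nearly marks that pair. Relative to each gene's mean it was 0.43 and 0.45 in hBD-2 1 and hBD-2 3, and -0.20 to -0.079 in the other arrays.

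Macrophage markers were lower as a group. The monocyte and macrophage list, with 20 members measured, fell by 0.37 on average (camera adjusted p = 3.89e-09, adjusted p = 0.0961 with an estimated correlation). Its mean per mouse was 0.19 ± 0.074 in PBS and -0.19 ± 0.054 in hBD-2 mice relative to each gene's mean (SD, n = 4), with no overlap. Of the 20 members 11 fell and 1 rose adjusted over the list alone, 8 did not pass, and none passed over all genes. The mannose receptor Mrc1 changed by -0.72 (SE 0.11), the integrin Itgax by -0.73 (SE 0.13), and the complement components C1qa by -0.66 and C1qc by -0.55. The member that rose was Timd4, a phosphatidylserine receptor of resident macrophages, at 0.24, named here after its values were seen. Without hBD-2 1 and hBD-2 3 the list stood at -0.35 (camera adjusted p = 4.52e-08).

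Chemokines fell by 0.26 on average over 27 members (camera adjusted p = 6.21e-07, adjusted p = 0.0961 with an estimated correlation), and this list and the macrophage list were those that passed fry (adjusted p = 0.0465 and 0.0123). Adjusted over the list alone 4 members fell, 23 did not pass, and none passed over all genes. Ccl3, which attracts monocytes and T cells, changed by -0.94 (SE 0.15), the monocyte attractant Ccl2 by -0.51, Ccl12 by -0.69 and the stromal chemokine Cxcl12 by -0.40. The neutrophil attractants Cxcl1 and Cxcl2 were at -0.31 (SE 0.19) and -0.25 (SE 0.24), without passing, and at -0.14 without hBD-2 1 and -0.058 without PBS 1, respectively. The receptors Ccr2 and Ccr6 were at -0.26 and 0.017, and neither passed.

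Inflammatory cytokines and NF-kB targets fell by 0.23 over 26 members (camera adjusted p = 8.90e-04, adjusted p = 0.304 with an estimated correlation). Tnfaip2, a TNF-induced gene, fell by 0.76, the adhesion molecule Vcam1 fell by 0.59 and the cytokine Il1b fell 2.01-fold, adjusted over the list alone, while 23 members did not pass and none passed over all genes. Tnf stood at -0.35 (SE 0.12) and Il6 at -0.73 (SE 0.36), without passing. The immediate early and heat shock list changed by -0.11 (camera adjusted p = 0.0211) and the endoplasmic reticulum stress list by -0.095 (camera adjusted p = 0.0213), with adjusted p = 0.427 and 0.243 with an estimated correlation. In neither did a member pass, with the transcription factor Jun at -0.24, Zfp36 at -0.27, Ier3 at -0.39, Hsph1 at -0.29, Atf4 at -0.20, Asns at -0.31, Chac1 at -0.35 and Trib3 at -0.35. Without hBD-2 1 and hBD-2 3, Jun was at -0.16, Ier3 at -0.022, Asns at -0.12, Chac1 at -0.059 and Trib3 at 0.00095. The immediate early call ended without PBS 2 (-0.059), hBD-2 2 (-0.12) or hBD-2 4 (-0.094) and grew without PBS 4 (-0.19). The endoplasmic reticulum stress call ended without PBS 3 (-0.087), hBD-2 2 (-0.092) or hBD-2 4 (-0.097), and both calls ended with quantile normalization repeated (-0.085 and -0.084) and with the lowest 25% of probe sets left out, where the means stayed at -0.11 and -0.095 (adjusted p = 0.0655 each), or the lowest 50% (-0.11 and -0.067).

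**Figure D3:**
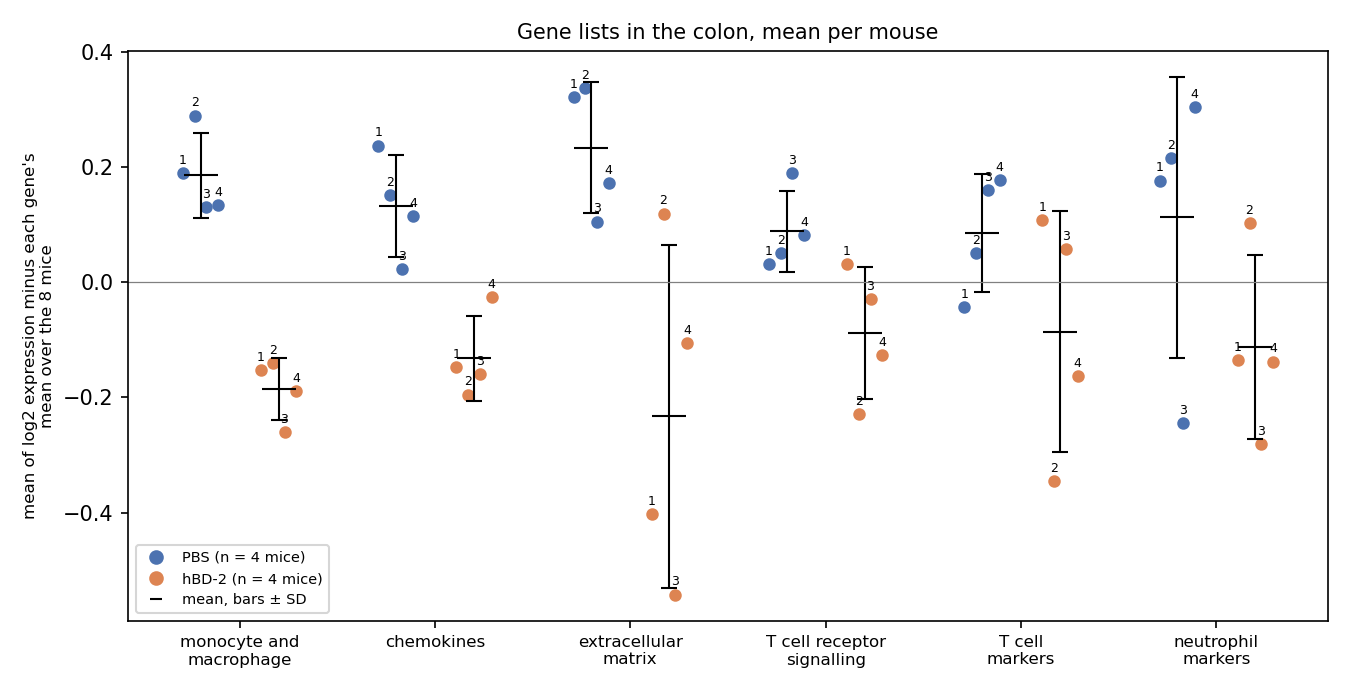
Mean of 6 gene lists per mouse (vertical axis: mean of log2 expression minus each gene's mean over the 8 mice), with 1 point per mouse, the replicate number above it, and the mean with SD for PBS (blue, n = 4) and hBD-2 (orange, n = 4). The groups do not overlap for the macrophage list (0.19 against -0.19 on average) or the chemokines (0.13 against -0.13), and they overlap for T cell and neutrophil markers.

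T cell receptor signalling genes, chosen because donor T cells drive the disease, fell by 0.18 on average over 27 members (camera adjusted p = 4.94e-06, adjusted p = 0.304 with an estimated correlation). Adjusted over the list alone 4 members fell, 23 did not pass, and none passed over all genes. Those 4 were Ctla4 at -0.63 (SE 0.13), Lcp2 at -0.66 (SE 0.14), Rasgrp1 at -0.38 and Ptpn6 at -0.29. Lcp2 and Rasgrp1 carry the signal of the receptor, whereas Ctla4 and the phosphatase Ptpn6 restrain it. The kinase Zap70 and the adaptor Lat stood at -0.19 (SE 0.12) and -0.050 (SE 0.098), without passing, and without hBD-2 2 Zap70 was at -0.056. The list stood at -0.27 without hBD-2 1 and hBD-2 3, and fry gave an adjusted p of 0.0902 over all 8 arrays.

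T cell markers fell by 0.17 over 16 members (camera adjusted p = 6.68e-03, adjusted p = 0.449 with an estimated correlation). The interleukin-7 receptor Il7r, at -0.63 (SE 0.089), and the co-receptor Cd4, at -0.61 (SE 0.11), fell adjusted over the list alone, 14 members did not pass, and none passed over all genes. Icos and Cd3d were at -0.35 and -0.30, the second at -0.19 without hBD-2 2. Cd3e, a chain of the receptor complex, was at -0.16 (95% interval -0.53 to 0.21, and -0.030 without hBD-2 2) and Cd8a, the co-receptor of cytotoxic T cells, at -0.048 (95% interval -0.49 to 0.39). Without hBD-2 2 the list was at -0.085 and the call ended (adjusted p = 0.151), as it did without PBS 4 (-0.14, adjusted p = 0.0501) and with array weights (-0.11), whereas the list stood at -0.31 with the lowest 50% of probe sets left out and without hBD-2 1 and hBD-2 3 at -0.34.

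Regulatory T cell genes fell by 0.20 (camera adjusted p = 8.59e-03, adjusted p = 0.243 with an estimated correlation). Ctla4 and the costimulatory receptor Tnfrsf4, at -0.48, fell adjusted over the list alone, and Lrrc32 at -0.35, Ebi3 at -0.28 (0.033 without hBD-2 1 and hBD-2 3) and the other members did not pass. The cytokine Il10 was at -0.0036 (95% interval -0.23 to 0.22). The regulatory list stood at -0.15 without hBD-2 1 and hBD-2 3, and its call ended (adjusted p = 0.111).

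Cytotoxic lymphocyte genes fell by 0.19 (camera adjusted p = 2.21e-03, adjusted p = 0.334 with an estimated correlation), with none of 18 members past. Tbx21, the transcription factor of type 1 T cells, was at -0.26, the granzyme Gzmc at -0.38, the receptor Klrk1 at -0.29 and Cxcr6 at -0.59. The interferon-gamma response changed by -0.11 (camera adjusted p = 5.33e-03, adjusted p = 0.577 with an estimated correlation), with none of 23 members past and Cd274, which encodes PD-L1, at -0.34, Iigp1 at -0.29, Gbp4 at -0.29 and Irgm2 at -0.19. Ifng itself was at -0.055 (95% interval -0.43 to 0.32). Without hBD-2 2 the cytotoxic list was at -0.11 and the interferon-gamma list at -0.011, and both calls ended (adjusted p = 0.0629 and 0.491), the first also with the lowest 50% of probe sets left out (-0.26, adjusted p = 0.146). The interferon-gamma list was at -0.17 without hBD-2 1, and without hBD-2 1 and hBD-2 3 the lists stood at -0.31 and -0.24.

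Fibroblast and extracellular matrix genes had the lowest camera p-value of the 43 lists. They fell by 0.47 on average over 24 members (camera adjusted p = 1.09e-14, adjusted p = 0.243 with an estimated correlation). Adjusted over the list alone 13 fell, 11 did not pass, and none passed over all genes. Vim, the intermediate filament of mesenchymal cells, changed by -0.54 (SE 0.095), the collagen Col3a1 by -0.52 (SE 0.091), periostin (Postn) by -0.53 (SE 0.10) and lumican (Lum) by -0.87 (SE 0.20). Without hBD-2 1 and hBD-2 3 the list stood at -0.23 (camera adjusted p = 2.35e-06) and with the posterior colon covariate at -0.17, and over all 8 arrays the exact permutation p of its mean was 0.0571.

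Endothelial genes fell by 0.22 (camera adjusted p = 5.18e-05, adjusted p = 0.243 with an estimated correlation). Of 18 members 5 fell adjusted over the list alone, among them the endothelial cadherin Cdh5 at -0.48, P-selectin (Selp) at -0.71, endoglin (Eng) at -0.57 and Pecam1 at -0.43. Without hBD-2 1 and hBD-2 3, Eng was at -0.30. None passed over all genes. Enteric neuron and glia genes changed by -0.11 (camera adjusted p = 0.0145, adjusted p = 0.459 with an estimated correlation), with no member past and Elavl4 at -0.46, Prph at -0.35, Stmn2 at -0.27 and Nefm at -0.20. The neuron call ended without hBD-2 1 and hBD-2 3 (-0.11, adjusted p = 0.105), without PBS 1 (-0.064), PBS 4 (-0.11), hBD-2 3 (-0.070) or hBD-2 4 (-0.078), and with the lowest 25% (-0.10) or 50% (-0.080) of probe sets left out. Without PBS 2 it stood at -0.18, and the endothelial list was at -0.14 with the posterior colon score as a covariate.

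Neutrophil markers, a readout of tissue damage in this disease, changed by -0.23 on average over 22 members (camera adjusted p = 0.0478, adjusted p = 0.531 with an estimated correlation, exact permutation p = 0.171). No member passed adjusted over the list alone or over all genes. At an unadjusted p under 0.05, 7 members were lower and 3 higher. The integrin Itgam was at -0.62 (SE 0.16), the calprotectin subunits S100a9 and S100a8 at -0.74 (SE 0.21) and -0.77 (SE 0.33), and the collagenase Mmp8 at -0.83 (SE 0.27). Elane, the elastase of neutrophil granules, was at 0.34 (SE 0.11), and Mpo at 0.12 (SE 0.099). Without hBD-2 1 and hBD-2 3, Itgam was at -0.29 and Elane at 0.19, and without PBS 4 S100a8 was at -0.48. The list's call ended without PBS 1, PBS 2, PBS 4, hBD-2 3 or hBD-2 4 taken singly, when the list stood at -0.20, -0.19, -0.16, -0.17 and -0.22, without hBD-2 1 and hBD-2 3 together (-0.13), and with the lowest 25% of probe sets left out (-0.27) or array weights (-0.23). Without PBS 3 it stood at -0.34 (camera adjusted p = 0.000226).

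Colonocyte genes rose by 0.24 over 29 members (camera adjusted p = 6.68e-03, adjusted p = 0.359 with an estimated correlation), and goblet cell genes rose by 0.19 over 22 (camera adjusted p = 6.68e-03, adjusted p = 0.427 with an estimated correlation). No member of either passed adjusted over the list alone. The carbonic anhydrase Car4 was at 0.39 (SE 0.12), the chloride and bicarbonate exchanger Slc26a3 at 0.33, Scnn1g at 0.85 (SE 0.44, but 0.41 without hBD-2 1 and -0.073 without hBD-2 1 and hBD-2 3) and the butyrate transporter Slc5a8 at 0.36 (0.16 without PBS 2). Among goblet genes the mucin glycosyltransferase St6galnac1 was at 0.34, Bcas1 at 0.36, Klk1 at 0.70 and Creb3l1 at 0.35, and the major mucin Muc2 was at 0.077 (95% interval -0.10 to 0.26). Without hBD-2 1 and hBD-2 3 the colonocyte list was at 0.15 and the goblet list at 0.068, and both calls ended (adjusted p = 0.199 and 0.333). In the same setting Car4 was at 0.24, Slc26a3 at 0.18, Slc5a8 at 0.18, Klk1 at 0.37 and Creb3l1 at 0.22. St6galnac1 and Bcas1 moved by at most 1.5 times. The colonocyte call also ended without PBS 4 (0.21) and the goblet call without PBS 2 (0.14), and the goblet list was at 0.12 without hBD-2 1.

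Cholesterol and fatty acid synthesis rose by 0.16 (camera adjusted p = 1.69e-04, adjusted p = 0.427 with an estimated correlation), xenobiotic and steroid metabolism by 0.15 (camera adjusted p = 0.0101, adjusted p = 0.296 with an estimated correlation) and circadian clock genes by 0.17 (camera adjusted p = 0.0117, adjusted p = 0.334 with an estimated correlation). No member of the 3 lists passed adjusted over its list alone. The fatty acid desaturase Scd1 was at 0.74 (SE 0.19), Acly at 0.28, the mevalonate kinase Mvk at 0.19 and Insig1 at 0.29. Cyp3a13 was at 0.43, Ugt2b35 at 0.88, Sult1c2 at 0.29 and Tiparp at -0.28, and of the clock repressors Nr1d1 was at 0.43, Cry2 at 0.35, Per1 at 0.27 and Per3 at 0.35. Without hBD-2 1 and hBD-2 3, Ugt2b35 was at 0.19, Acly at 0.12 and Per1 at 0.15, and without PBS 4 Cyp3a13 was at 0.27. Leaving out hBD-2 1 and hBD-2 3 put these lists at 0.082, 0.23 and 0.14 and ended the calls (adjusted p = 0.224, 0.0522 and 0.223). The xenobiotic list was at 0.093 without PBS 4, which ended its call, and at 0.088 without hBD-2 2.

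Ribosomal protein genes changed by -0.064 (camera adjusted p = 0.0117, adjusted p = 0.393 with an estimated correlation), with no member past and Rplp1 at -0.16, Rps9 at -0.17, Rps18 at -0.15 and Rpl7 at -0.094. Mast cell and eosinophil genes rose by 0.12 (camera adjusted p = 0.0117, adjusted p = 0.243 with an estimated correlation), and the mast cell chymase Cma1, at 0.41 and with signals below the lower quartile of every array, rose adjusted over the list alone. The tryptase Tpsb2 was at 0.22, the eosinophil receptor Ccr3 at 0.23 and Hdc, which makes histamine, at -0.24. Pancreatic acinar genes, a check for neighbouring tissue, rose by 0.13 (camera adjusted p = 0.0148, adjusted p = 0.304 with an estimated correlation), with Cpa1 past over the list alone at 0.26, and Cela3b, Cela1 and Clps at 0.25, 0.35 and 0.18. Of the 14 pancreatic members measured, 0 lay above the median of all genes, so these small shifts do not show that neighbouring tissue was present. The ribosomal call ended without hBD-2 1 and hBD-2 3 (-0.050), the mast cell call without hBD-2 4 (0.10), and the pancreatic call without PBS 1 (0.10) or hBD-2 2 (0.10). With quantile normalization repeated the mast cell and pancreatic calls ended (0.082 and 0.090), and the mast cell call also ended with the lowest 25% of probe sets left out (0.030).

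The other 21 tested lists did not pass camera. Smooth and skeletal muscle genes were at -0.088 (adjusted p = 0.0512), with Mylk at -0.41 and Myl9 at -0.28. They passed without hBD-2 1 (-0.13) or hBD-2 2 (-0.12), but were at -0.0017 without hBD-2 3 and at -0.028 without hBD-2 1 and hBD-2 3. PPAR targets and fatty acid oxidation were at -0.13 (adjusted p = 0.0512), where Cd36 fell adjusted over the list alone and the coactivator Ppargc1a was at 0.75 (SE 0.25, but 0.26 without hBD-2 1 and hBD-2 3). That list passed without PBS 2 (-0.14), PBS 4 (-0.21) or hBD-2 2 (-0.17), and was at -0.072 without PBS 3 and at -0.024 without hBD-2 1 and hBD-2 3. Regenerating epithelium genes were at -0.12 (adjusted p = 0.0931), with Clu at -0.24 and Plaur at -0.49. They passed without PBS 3 (-0.15), and were at -0.073 without hBD-2 3 and at -0.044 without hBD-2 1 and hBD-2 3. Enteroendocrine genes were at 0.15 (adjusted p = 0.160), with Pcsk1 at 0.29 and Rfx6 at 0.18, but the list was at 0.063 without hBD-2 1 and at -0.058 without hBD-2 1 and hBD-2 3. Small intestinal and Paneth cell genes were at 0.12 (adjusted p = 0.167), and Anpep, the brush border aminopeptidase N, fell by 0.54 adjusted over the list alone, while Fabp6 was at 0.25. The p53 response and apoptosis list was at -0.041 (adjusted p = 0.180), with Phlda3 lower by that test, at -0.43, and Eda2r at -0.47. Among intestinal stem cell and Wnt genes, at -0.031 on average (adjusted p = 0.635), Myc fell by 0.46 and Bmi1 fell by 0.38, while Smoc2, named after its values were seen, rose by 0.38, each adjusted over the list alone, and the stem cell receptor Lgr5 was at 0.16 (SE 0.095). In the posterior colon list Hoxd12 rose by 0.36 adjusted over the list alone and Hoxd13 was at 0.83 (SE 0.42), or -0.085 without hBD-2 1 and hBD-2 3.

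In the remaining lists no member passed adjusted over the list alone. Antimicrobial peptides and proteins were at 0.047 (adjusted p = 0.374), with Reg4 at 0.81 (SE 0.28, but 0.39 without hBD-2 1 and hBD-2 3), Lyz1 at -0.47 and the mouse defensin Defb4 at 0.18 (SE 0.13). Reg3b and Reg3g, bactericidal lectins, were at -0.37 (SE 1.54) and 0.32 (SE 1.39), and their spread between mice left the direction open. Tight and adherens junctions were at 0.042 (adjusted p = 0.787), with Jam3 at -0.27, Tjp1 at 0.0039 (95% interval -0.21 to 0.22) and Ocln at 0.099 (95% interval -0.11 to 0.31). The type I interferon response was at 0.0071 (adjusted p = 0.930, but 0.11 and past the threshold without PBS 2), with Ifit3 at -0.26 and Oas3 at 0.20. MHC class II and antigen presentation was at -0.0043 (adjusted p = 0.919), with Flt3 at 0.40 and Ctss at -0.23. The IL-17 and IL-22 axis was at -0.0037 (adjusted p = 0.636), with Ahr at -0.26 and Il22ra2 at 0.32. Hypoxia and glycolysis was at 0.037 (adjusted p = 0.379), with Pdk1 at 0.55 and Pfkfb3 at -0.50, and oxidative phosphorylation at 0.038 (adjusted p = 0.186, but 0.062 and past the threshold without PBS 3), with Sdhc at 0.29 and Ndufv1 at 0.12. B and plasma cell markers were at 0.024 (adjusted p = 0.420), with Cd79b at 0.22 and Cr2 at -0.20. Tuft cell genes were at 0.024 (adjusted p = 0.636), with Pou2f3 at 0.25 and Hpgds at -0.27. The oxidative stress response was at 0.011 (adjusted p = 0.945), with Gsta3 at 0.34 and Slc7a11 at -0.59, and the cell cycle at 0.014 (adjusted p = 0.714), with Bub1 at -0.17 and Plk1 at 0.12. Red cell and platelet genes were at -0.0090 (adjusted p = 0.636), with Rhd at 0.24 and Tspan33 at 0.29, and adipocyte genes at -0.012 (adjusted p = 0.888), with Fabp4 at -0.34 and Ucp1 at -0.15. The innate receptor Tlr4 was at -0.15 (SE 0.084). Mean, median and test did not share a sign for the stem cell, red cell, junction, IL-17, MHC class II, type I interferon and adipocyte lists. Leaving out single arrays turned the direction of the antimicrobial, tuft cell, type I interferon, MHC class II, IL-17, oxidative stress, cell cycle, red cell and adipocyte lists. Leaving out hBD-2 1 and hBD-2 3 together turned the junction, oxidative phosphorylation, stem cell, enteroendocrine, IL-17, cell cycle, red cell and adipocyte lists. The sex-linked list had 3 members measured, below the minimum of 5 for a test, and Uty, Kdm5d and Eif2s3y lay between 2.95 and 3.76 log2 units in all 8 arrays.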

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

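Within each group of 4 mice, a value was singled out when its gap to the nearest other mouse exceeded 0.829 of the group's range (Dixon's test). Chance singles out about 1 in 20 groups. Of 86 list groups 4 were singled out, where chance gives 4.3, and of 348 gene groups 16, where chance gives 17.4. The number is thus no larger than chance gives, and no explanation is weighed for single values. There was no second tissue or time point in which to compare the effect of hBD-2.

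Among list means, PBS 4 lay low for the cell cycle at -0.098 (gap ratio 0.859), and PBS 3 lay high for the posterior colon identity genes at -0.079, against -0.20 in the others (0.966). In the hBD-2 group, hBD-2 4 lay low for cholesterol and fatty acid synthesis at -0.12 (0.855), and hBD-2 2 lay high for xenobiotic and steroid metabolism at 0.27 (0.838).

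Among genes of the PBS group, PBS 3 lay high for Ccl3 at 8.90 log2 units (0.842) and Jun at 9.46 (0.861). PBS 4 lay low for Ccl12 at 7.82 (0.940) and high for Selp at 7.26 (0.878). PBS 2 lay low for the chymase Cma1 at 3.92 (0.835), and PBS 1 lay low for Cd3e at 7.98 (0.832).

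In the hBD-2 group, hBD-2 2 lay high for the macrophage receptor Mrc1 at 9.67 (0.864) and for Lrrc32 at 6.20 (0.857), and low for Klrk1 at 5.32 (0.861) and the T cell kinase Zap70 at 5.84, against 6.36 to 6.38 in the other 3 (0.964). hBD-2 4 lay low for Insig1 at 9.80 (0.843), for the goblet cell factor Creb3l1 at 9.99 (0.935) and for Reg4 at 10.4, against 11.6 to 11.9 in the others (0.833). hBD-2 1 lay high for Bcas1 at 9.28 (0.926) and low for Pcsk1 at 4.70 (0.884), and hBD-2 3 lay low for Clps at 6.34 (0.881).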

How the results depend on the processing

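The number of genes past the threshold, 8 and all lower, changed with the setting, and in several settings none passed. It was 91 with an intensity trend and robust prior (85 lower), 68 with array weights (59 lower) and 16 with the lowest 25% of probe sets left out (15 lower), each including the 8. With the lowest 50% left out it was 47 (46 lower, 6 shared, Aif1 and Clec5a not tested). Quantile normalization repeated gave 4, all shared, all probe sets 5, a threshold of 0.1 gave 81, and a log2 minimum of 1 gave 0. Median centring and averaged probe sets gave 8 each, and the posterior colon covariate 11 (9 lower, 1 shared). Leaving out single arrays gave 0 to 11 genes (0 in 6 cases) and 17 to 23 lists. With the replicate block 0 genes and 23 lists passed (2566 genes at an unadjusted p under 0.05 in limma). Same-numbered samples correlated at -0.152, 0.139, 0.244 and 0.0454 in their deviations from the group means, and differently numbered ones at -0.252 to 0.199. These values do not settle whether the numbers pair the mice, and the main fit left the mice unpaired. Without hBD-2 1 and hBD-2 3 limma passed 0 genes (2503 at an unadjusted p under 0.05). For lists, 0 of 43 passed with an estimated correlation, 2 by fry, and 13 each without those arrays and with the covariate. The neutrophil list was at -0.27 (lowest 25% left out), -0.23 (array weights), -0.23 (estimated correlation, and fry), -0.13 (without hBD-2 1 and hBD-2 3) and -0.067 (covariate), each without passing, and between -0.34 and -0.16 with single arrays left out. With the lowest 50% left out it had too few members for a test. The T cell receptor list (-0.18) and matrix list (-0.47) lost their calls with the estimated correlation and by fry, the macrophage list (-0.37) and chemokines (-0.26) with the estimated correlation alone. Where fewer samples or genes do not account for a change, the cause was not tested. Signal over background is unknown, so what dim probe sets limit was tested through the filters alone.

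Of the uncalled lists, muscle genes passed in 7 settings and PPAR targets in 6, all lower, oxidative phosphorylation in 2, and regenerating epithelium and type I interferon in 1 each. Among the settings tried, none of the 22 called lists or 8 called genes changed sign. Sign changes among uncalled results were as follows, and their cause was not tested. With the lowest 25% left out, tuft cell genes were at -0.00068 and red cell and platelet genes at 0.057. With the lowest 50% left out, MHC class II was at 0.013, antimicrobial genes at -0.022, oxidative stress at -0.0070 and red cell genes at 0.014. Median centring put MHC class II at 0.016, the IL-17 axis at 0.016, adipocyte genes at 0.0081, red cell genes at 0.011 and Il10 at 0.016. Array weights put MHC class II at 0.0043, type I interferon at -0.0085, the IL-17 axis at 0.00029, Ifng at 0.022, Cd8a at 0.043 and Reg3g at -0.53. Repeated quantile normalization put B cell markers at -0.015, tuft cell genes at -0.00080 and Ccr6 at -0.035. Without hBD-2 1 and hBD-2 3, the IL-17 axis was at 0.0045, junctions at -0.0089, stem cell genes at 0.014, enteroendocrine genes at -0.058, the cell cycle at -0.018, oxidative phosphorylation at -0.00017, adipocyte genes at 0.12 and red cell genes at 0.11. Among genes it put Scnn1g at -0.073, Ebi3 at 0.033, Trib3 at 0.00095, Hoxd13 at -0.085, Il10 at 0.031, Reg3b at 2.48, Tjp1 at -0.16 and Ocln at -0.029. The covariate put the IL-17 axis at 0.013, junctions at -0.026, stem cell genes at 0.019, enteroendocrine genes at -0.11, the cell cycle at -0.027, hypoxia and glycolysis at -8.8e-05, oxidative phosphorylation at -0.016, adipocyte genes at 0.14 and red cell genes at 0.13. It put Scnn1g at -0.23, Ebi3 at 0.12, Ier3 at 0.048, Trib3 at 0.080, Hoxd13 at -0.26, Cxcl1 at 0.0053, Cxcl2 at 0.082, Il10 at 0.056, Reg3b at 3.35, Tjp1 at -0.18 and Ocln at -0.071.

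Leaving out single arrays gave ranges across 0 for MHC class II (-0.044 to 0.070), type I interferon (-0.049 to 0.11), the IL-17 axis (-0.023 to 0.014), antimicrobial genes (-0.038 to 0.12), tuft cell genes (-0.019 to 0.071), the cell cycle (-0.016 to 0.028), oxidative stress (-0.022 to 0.036), adipocyte genes (-0.059 to 0.058) and red cell genes (-0.065 to 0.038). Among genes they did so for Ifng (-0.18 to 0.078), Cd8a (-0.17 to 0.093), Lat (-0.11 to 0.016), Il10 (-0.057 to 0.073), Reg3b (-1.42 to 0.84), Reg3g (-0.65 to 1.23), Tjp1 (-0.065 to 0.068) and Ccr6 (-0.084 to 0.067).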

Other observations

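The gene families in this part and the tests of explanations were chosen after the results were seen, and the counts of splits of the mice were planned.

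Of 5 measured genes for Fc gamma receptors and their signalling chain, all 5 were lower and 4 fell adjusted over the family alone. Fcgr4 changed by -1.09 (SE 0.22), Fcer1g by -0.81, the inhibitory receptor Fcgr2b by -0.72 (SE 0.15) and Fcgr3 by -0.70 (SE 0.13), and the high-affinity receptor Fcgr1 was at -0.042 (SE 0.096). Over all genes Fcer1g passed and the other 4 did not, with limma adjusted p from 0.0874 to 0.891. Of 12 Toll-like receptors, Tlr7, a sensor of single-stranded RNA, fell by 0.96 (SE 0.16) and Tlr13, a sensor of bacterial ribosomal RNA, fell by 0.82 (SE 0.13), adjusted over the family alone. Neither passed over all genes (limma adjusted p = 0.0707 and 0.0634). The other 10 did not pass, with Tlr8 at -0.37 (SE 0.16), Tlr2, which binds bacterial lipoproteins, at 0.029 (SE 0.11), Tlr3 at -0.035 (SE 0.080) and Tlr9 at -0.049 (SE 0.083). Of 7 bone morphogenetic proteins Bmp5 fell by 0.63, and no other passed, with Bmp4 at -0.31 (SE 0.17) and Bmp7 at -0.34 (SE 0.17).

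Cd4 set against the mean of Cd3d, Cd3e, Cd3g, Cd247 and Cd2 in the same mouse was 1.08 ± 0.15 in PBS and 0.69 ± 0.20 in hBD-2 mice (SD, n = 4), a difference of -0.39 (two-sided exact permutation p = 0.0571). Reg3b ranged from 5.66 to 12.5 log2 units over the 8 mice. It was at 12.1, 10.5, 6.98 and 9.16 in PBS 1 to 4 and at 7.25, 12.5, 5.66 and 11.9 in hBD-2 1 to 4. Its relative Reg3g lay at 9.94, 7.74, 4.91 and 7.10, and at 5.40, 10.6, 5.02 and 9.92.

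The first pattern is the distance of hBD-2 1 and hBD-2 3 from the other arrays. Poorer arrays are argued against, since 2 of the other 6 had a wider spread of relative log expression than either. Another position along the colon is a candidate explanation. It was examined in the mean of Scnn1b, Scnn1g, Atp12a, Fxyd4 and Aqp8, distal transport genes listed after the principal components had been seen. Scnn1g was among the genes named by rule, whose values per mouse were computed together with the principal components. All but Fxyd4 (4 of them) are also in the colonocyte list, whose mean had been seen. The lower of the pair lay 1.08 log2 units above the highest other array. This gap is therefore not an independent test of position. Among 4 measured genes listed as proximal, Mettl7b, Fabp2 and Cyp2c55 were low in the pair (Cyp2c55 at 4.80 and 4.89, although PBS 4 was at 4.75), but Aqp4 was high, at 10.7 and 10.8. An effect of hBD-2 in these mice alone stays open, since both arrays are of the treated group. The tissue is described only as whole colon tissue, and no label used here says which part of the colon each array represents.

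The second pattern is the lower macrophage list, for which a different colon position of those arrays is argued against as the whole cause, since without them it stood at -0.35, against -0.37 with them. Dilution by epithelium stays open: the list fell by more than the mean of the other 12 non-epithelial cell type lists (difference -0.24), but against the 5 of them with no fewer members above the median of all genes than below it the difference was -0.18 (two-sided exact permutation p = 0.0286 for both, the smallest possible), short of the -0.2 set as the bound. The muscle list, among those 5, was at -0.088 and the matrix list at -0.47, and 10 pan-epithelial genes were at -0.034 (exact p = 0.343), at a level of 11.3 log2 units where a small rise in their share would hardly show. Chance is not excluded, as the exact permutation p of the macrophage list was 0.0286 and became 0.123 adjusted over the lists. Fewer macrophages or lower expression per macrophage in hBD-2 mice may both be behind it, as hypotheses that whole tissue cannot separate.

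The third pattern is the lower matrix list. Without hBD-2 1 and hBD-2 3 it stood at -0.23, against -0.47 with them, so colon position and treatment cannot be told apart for it: the arrays that carry the larger part are both treated and apart in position genes. Chance is not excluded either (two-sided exact permutation p = 0.0571), since the split that exchanged PBS 3 with hBD-2 2 gave a change of 0.474, against 0.466 in the real split.

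Over all genes and lists, 1 of the 35 splits, the real one, gave 8 or more genes past the threshold (highest other 5), 2309 or more at an unadjusted p under 0.05 (highest other 2265) and 22 or more lists (highest other 18). First place among 35 is the most this design can give, and the margins were narrow, so chance is argued against but not excluded. For single lists chance is not excluded either, since the exact permutation p of the chemokine and T cell receptor signalling lists was 0.0286, or 0.123 adjusted over the lists, and that of the neutrophil list was 0.171.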
